A study of Homo sapiens with 8 samples.

How the data were processed

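RNA was sequenced from 8 colonies of epithelial cells cultured from human urine, each a separate clone per the labels, with 1 library per colony. Per the labels' protocols, colonies of about 50000 to 150000 primary cells in renal epithelial growth medium were taken 2 to 3 weeks after plating, polyadenylated RNA was selected, ribosomal sequences were removed, and libraries were read as read pairs on a HiSeq 2500. The labels call all colonies untreated and wild type, so there is 1 group and no contrast between groups. Whether the colonies share a donor was not given in the sources used here.

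The authors deposited a table of raw read counts per gene, and per the submitters' processing notes the tools used were STAR, SAMtools, HTSeq and DESeq2 with the genome build GRCh38. Their versions, the annotation release, the counting mode and the use of strand were not given in the sources used here. The authors also deposited a table of normalized signal, which was found to equal the raw counts divided by 1 size factor per library (0.602, 0.922, 1.93, 0.946, 0.798, 0.847, 1.02 and 1.47 for colonies 1 to 8, with a relative range of the ratio of at most 1.41e-09). These factors equal those that DESeq2 gave here from the raw counts. All values in the report were computed from the raw counts. The tables hold 58051 genes, of which 57447 have an Ensembl identifier in GENCODE release 29 and 22882 have no symbol. All 436 genes of the lists were found, 5 of them by the Ensembl identifier of their current symbol, because the tables give an older symbol.

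Libraries held 12839334 to 31881089 counts (mean 18643185), with 24656 ± 1463 genes detected and 13359 ± 196 genes at 1 CPM or more (SD, n = 8). The clustered protocadherins together had 1370 to 5599 counts per library. Of the counts, 27.9% ± 6.11 were mitochondrial ribosomal RNA, 4.94% ± 1.96 FN1 and 0.791% ± 0.202 mitochondrial mRNA (SD, n = 8). A count of 0 was taken to allow up to 3 counts, which sets the lowest measurable level at 0.0844 to 0.277 CPM, and folds against a count of 0 are given as at least that large. Correlations of log2 profiles between colonies had a median of 0.896 for colony 8 with the others, and the first 2 principal components held 32.2% and 24.7% of the variance. Libraries were checked for duplicates by the chi-square of raw counts over genes for each of the 28 pairs.

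CPM values used TMM factors of edgeR 4.0.16, in R 4.3.3 with limma 3.58.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the remaining steps, and DESeq2 1.42.0 for alternatives. Log2 values had 0.5 CPM added. An isoform counted as expressed at 1 CPM or more. Sharing of isoform sets was tested with 10000 random matrices that kept both margins, and against 2000 draws with equal chance for each isoform. Totals of the clusters and levels of the lists were compared within colonies by exact sign-flip tests, whose smallest p is 0.00781 with 8 colonies and 0.0156 with 7. Correlations used exact permutations of the pairings and were repeated without the 2 colonies farthest from the median of the first variable. Position used 100000 permutations and neighbours 10000 shuffled orders. The Benjamini-Hochberg method was used within each family of tests, at 0.05.

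Variability was measured with an intercept-only quasi-likelihood fit in edgeR, after filterByExpr, as the ratio of the gene's quasi-dispersion to its trend, with a one-sided F test. In 1 group of 8, filterByExpr asks for enough counts in every colony, which left 12442 genes and 6 of the 53 clustered protocadherins. For this reason values with a filter at a mean of 1 CPM, an alternative fixed before the data were read, stand beside those of the planned filter. Lists were compared with 10000 random lists of equal size matched on mean log CPM in 20 bins (smallest p 0.0002). The 29 lists fixed before the data were read cover the 5 protocadherin classes, nonclustered protocadherins, other contact genes, regulators, housekeeping genes, 13 sets of cell type markers and 7 sets of kidney, HOX, cell cycle, stress, inflammatory, imprinted and mitochondrial genes. The 5 protocadherin classes were also pooled. Lists with fewer than 3 genes kept were not tested, which left 20. Level and variability of lists not described in the report are given under other observations.

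The rule for named genes, fixed before the data were read, takes the 4 isoforms of each protocadherin class with the highest mean and the 4 with the highest ratio, the 25 genes with the highest ratio among those with a symbol and a mean log2 CPM above 2, and in each other list the 3 members with the highest mean and the 2 with the highest ratio. PCDHB7, PCDHB9, PCDHGB1, PCDHGB2, COL1A1, COL1A2, COL3A1, ACTA2, DCN, DES, PDGFRA, ITGA8, NPHS1, HOXA11, HOXD10, HOXD11, CLIC5, FOXC1, PLA2R1 and MKI67 fall outside it and were chosen after their values were seen. Sex-linked genes, HLA and immune receptor genes and genes with common germline deletions were left out of the named genes. Some genes that the rule or the lists cover are not reported here by name, and these were also left out of the search for colonies that lay apart.

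Exonic positions and first-exon sequences came from GENCODE release 29 on GRCh38. Exonic bases shared with no other gene, over all annotated transcripts, served as the length of an isoform. This alternative was chosen after the data were seen. Shared sequence is the percent of 50-base words of a first exon that occur in transcripts of other genes. The random seed was 7, and thinned libraries held 12839334 counts each.

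The tests were run on simulated data. With the scatter of the real fit, 200 of 12442 genes given an added log2 SD of 1 or 2 were recovered in 0% and 0% of cases after adjustment (16% and 84% at an unadjusted p under 0.05), and without gene scatter in 25% and 91%, with 0 false calls (edgeR). In these simulated counts the list test gave a p under 0.05 in 7% of null lists with gene scatter and 2% without. In a separate simulation it did so in 4% of null lists and 78% of lists raised by a log2 ratio of 1. The rates were 3.33% and 100% for similarity, 3% and 100% for neighbours, 7% and 100% for position, 4.40% and 99.6% for the sign-flip test, 6% and 98% for the pairings, and 6.67% and 100% for sharing with both margins kept. The equal-chance model called 96.7% of simulated independent colonies with unequal isoform use, so it tests unequal use rather than shared identity.

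Alternatives fixed before the data were read were other thresholds, median-of-ratios factors or total counts, thinned libraries, a pseudocount of 2 CPM, other filters, other measures of variability, sums without C-type isoforms and leaving out each colony. With 1 group, values were paired only within colonies, in the sign-flip tests. Reads were not aligned again.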

Results

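Cells shed into human urine were grown in culture, and RNA was sequenced from 8 colonies, each a separate epithelial clone per the labels, with 1 library per colony. The labels give the tissue as renal glomerulus, the filtering unit of the kidney, and name neither a treatment nor a second group, so all comparisons were made between colonies or between genes within colonies. The total counts over genes were 12839334 in colony 1, 16798289 in colony 2, 31881089 in colony 3, 15469235 in colony 4, 16155746 in colony 5, 16502352 in colony 6, 17992792 in colony 7 and 21506644 in colony 8. Mitochondrial ribosomal RNA took 27.9% ± 6.11 of these counts (SD, n = 8) and FN1, which encodes the matrix protein fibronectin, took 4.94% ± 1.96 (SD, n = 8). A count of 0 in a library allowed a level of up to 0.0844 to 0.277 CPM (counts scaled by library size), depending on its depth. No pair of libraries agreed within counting noise, since the chi-square per degree of freedom was at least 21.1 over all 28 pairs. Whether the colonies came from 1 donor or from several was not given in the sources used here, and with 1 library per colony the technical spread is part of the spread between colonies. Intervals and limits below cover counting error only, because amplified reads without molecular identifiers are not independent molecules.

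The series title speaks of names by which podocytes avoid themselves, and the first question was whether each clone expressed its own set of clustered protocadherins. These cell adhesion proteins bind their own kind on neighbouring cells, and neurons use combinations of them to tell their own processes from those of other cells. Their 53 genes lie in 3 clusters on chromosome 5 (GRCh38), with 15 alpha isoforms at 140786136 to 141012347, 16 beta isoforms at 141051135 to 141249365 and 22 gamma isoforms at 141330571 to 141512981. At a threshold of 1 CPM, the colonies expressed 29, 29, 23, 33, 24, 22, 11 and 15 isoforms, in the order of their numbers, or 23.3 ± 7.38 of 53 (SD, n = 8). The mean number was 5.88 ± 2.36 for alpha, 7.50 ± 4.00 for beta and 9.88 ± 4.09 for gamma (SD, n = 8). All 8 sets were distinct, but sets of 11 to 33 isoforms out of 53 would hardly ever coincide by chance. This count was not compared with random sets, so it does not show that a set was particular to a clone. PCDHA10, PCDHA11, PCDHAC2, PCDHB2 and PCDHGC3 reached the threshold in all 8 colonies, 9 isoforms reached it in 1 colony and 7 in none. Each library pooled the RNA of a colony of about 50000 to 150000 cells. Cells that share 1 set therefore cannot be told from cells of a colony that differ in their isoforms.

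**Figure D1:**
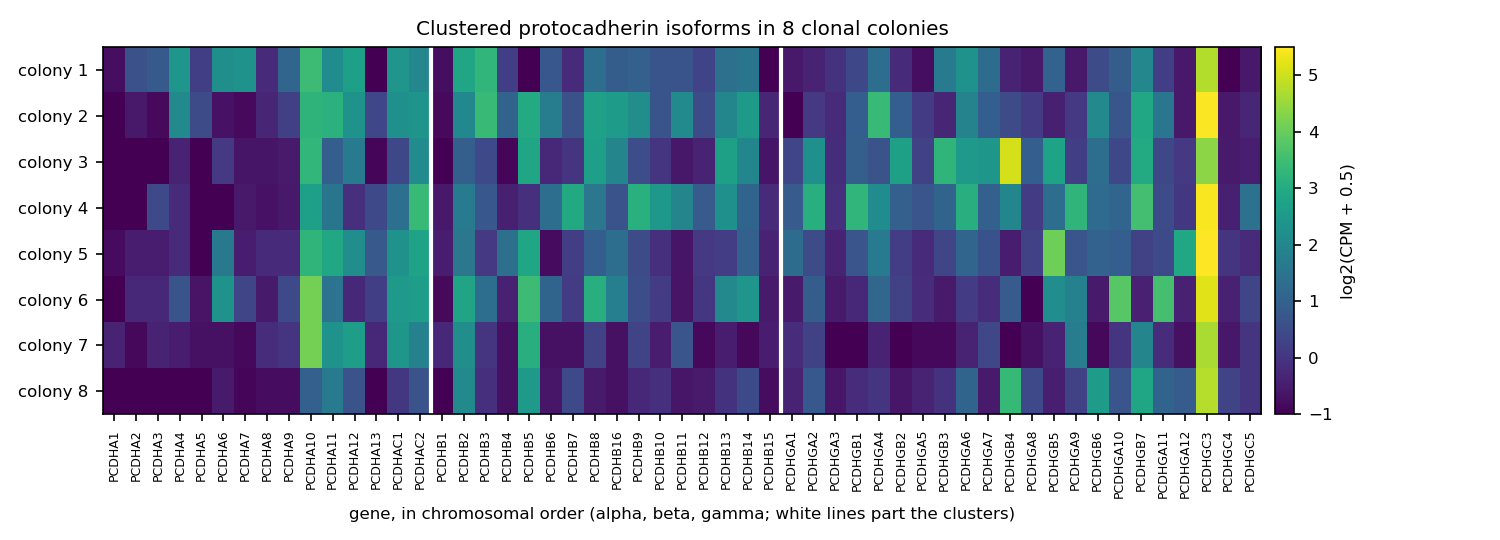
Level of each of the 53 clustered protocadherin isoforms, as log2(CPM + 0.5) on the colour scale, in chromosomal order on the horizontal axis and with the 8 colonies as rows. PCDHGC3 was bright in every colony, while others such as PCDHGB4 (33.3 CPM in colony 3) were bright in few.

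The number of isoforms depended on the threshold, with a mean of 31.0 at 0.5 CPM and 7.75 at 5 CPM. Overlap between colonies was compared with random sets in which each colony kept its number of isoforms and each isoform its number of colonies. The mean Jaccard index, the shared fraction of a pair's combined set, was 0.433 over the 28 pairs, against 0.432 for the random sets (95% range 0.429 to 0.435, two-sided permutation p = 0.424). Keeping both numbers leaves this mean little room to move. In simulations the test still called 100% of cases with 2 blocks of colonies that used different isoforms, and 6.67% of cases with independent colonies. Weaker grouping was not simulated, so a value near random leaves it open. The SD of the index between pairs, which keeping both numbers does not fix, was 0.104 against 0.110 (two-sided permutation p = 0.635). At 0.5 CPM the mean index was 0.540, against 0.537 for random sets, and the two-sided permutation p was 0.0194. Against a model in which all isoforms were equally likely, the random index was 0.269 (0.249 to 0.291) and the permutation p was 0.001, the smallest that the draws could give, so isoforms differed in how many colonies used them. Total counts and isoform number had a Pearson r of -0.31 (exact permutation p = 0.467, n = 8) and a Spearman rho of -0.67 (exact permutation p = 0.0765, n = 8). Without the 2 colonies farthest from the median depth r was -0.64. With a threshold of 10 raw reads the direction turned, with r of 0.30 (exact permutation p = 0.411, n = 8) and rho of -0.06 (exact permutation p = 0.893, n = 8), and r was -0.44 without the 2 farthest colonies.

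The isoform with the most counts in each cluster, apart from the C-type genes, was compared next. C-type genes were also left out of the cluster counts that the percentages of leading isoforms refer to. Counts here and elsewhere were not divided by gene length. PCDHA10 led the alpha cluster in colonies 1 to 7, with between 27.01% of the alpha counts without C-type genes (95% Wilson interval 23.0 to 31.4) in colony 1 and 62.6% (58.4 to 66.6) in colony 3, and PCDHA11 led in colony 8 with 48.0% (40.1 to 56.0). In the beta cluster PCDHB3 led in colonies 1 and 2, PCDHB9 in colony 4, and PCDHB5 in the remaining 5, with 47.7% (42.2 to 53.3) in colony 7. In the gamma cluster 6 isoforms led: PCDHGA6 in colony 1, PCDHGA4 in colony 2, PCDHGB4 in colonies 3 and 8, PCDHGB7 in colonies 4 and 7, PCDHGB5 in colony 5 and PCDHGA10 in colony 6. PCDHGB4 took 38.3% (36.6 to 39.99) of the gamma counts without C-type genes in colony 3 and PCDHGB5 took 39.4% (35.5 to 43.4) in colony 5. The combination of the 3 leading isoforms differed between all 8 colonies, but this was not compared with random combinations. Some leads were narrow, with 144 counts of PCDHA10 against 137 of PCDHA11 in colony 2. In colony 4 PCDHB9 had 136 counts against 120 of PCDHB7, and in colony 1 PCDHGA6 had 49 against 38 of PCDHGB7. Many of these leads depend on whether counts are divided by length. Over all its annotated transcripts PCDHA10 has 9555 exonic bases shared with no other gene, against 3360 for PCDHA11 and 2011 for PCDHA12. Whether the expressed transcripts hold all of these bases was not tested. Per such base, PCDHA10 led in colony 6 only, PCDHA11 in colonies 2, 4, 5 and 8 and PCDHA12 in colonies 1, 3 and 7. The lead also passed to PCDHB8 in colony 3, PCDHB7 and PCDHGB1 in colony 4, PCDHGB7 in colony 1 and PCDHGA11 in colony 6, and the 8 combinations remained distinct.

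Single isoforms ranged widely between colonies. PCDHGB4 (ENSG00000253953, first base at 141387698) had 33.3 CPM in colony 3 and a count of 0 in colony 7, so it was at least 205-fold lower there, and its mean was 6.15 ± 11.4 CPM (SD, n = 8). PCDHGB1 had 9.24 CPM in colony 4 and a count of 0 in colony 7, at least 56.8-fold lower, and PCDHGB2 had 5.94 CPM in colony 3 and a count of 0 in colony 7, at least 36.5-fold lower. PCDHB5 (ENSG00000113209, 141135218 to 141138625) had 10.4 CPM in colony 6 and a count of 0 in colony 1, at least 37.5-fold lower. PCDHGB5 was highest in colony 5 at 16.3 CPM (mean 3.88 ± 5.45, SD, n = 8). PCDHGA10 and PCDHGA11 were both highest in colony 6, at 13.5 and 11.4 CPM, against means of 2.70 ± 4.39 and 2.38 ± 3.69 CPM (SD, n = 8). PCDHB3 had 9.13 CPM in colony 1 and 10.1 CPM in colony 2, against a mean of 3.10 ± 4.08 CPM (SD, n = 8). PCDHA10 (ENSG00000250120) had a mean of 9.88 ± 5.24 CPM (SD, n = 8), from 1.497 in colony 8 to 17.1 in colony 7. Alpha isoforms share their last exons with one another, as do gamma isoforms, and 58.5% of the 50-base words of the first exon of PCDHGB4 and 49.3% of those of PCDHB8 also occur in transcripts of other genes. The counting mode and the use of strand were not given in the sources used here, so the split of reads between such isoforms is uncertain.

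The gamma cluster gave the most protocadherin transcripts. The summed level was 76.4 ± 26.97 CPM for gamma, 31.7 ± 14.95 CPM for beta and 31.1 ± 13.1 CPM for alpha (SD, n = 8), 139 ± 36.7 CPM in all. PCDHGC3, a C-type isoform whose expression in neurons is not left to promoter choice, made up 47.1% ± 14.9 of all gamma counts, C-type genes included, and was the steadiest of the abundant isoforms at 33.2 ± 9.74 CPM (SD, n = 8). The other C-type isoforms were lower, with 4.81 ± 2.68 CPM for PCDHAC2, 3.39 ± 1.92 CPM for PCDHAC1 and 0.632 ± 0.669 CPM for PCDHGC5 (SD, n = 8). Beta lay below gamma in all 8 colonies, with a mean log2 difference of -1.32 ± 0.64 (SD, n = 8; exact sign-flip p = 0.00781, the smallest that 8 colonies allow, adjusted p = 0.0234 over 3 contrasts). Alpha lay below gamma in 7 colonies, by a mean log2 difference of -1.37 ± 1.11 (SD, n = 8; exact sign-flip p = 0.0234, adjusted p = 0.0352), and alpha minus beta was -0.05 ± 0.80 (SD, n = 8; exact sign-flip p = 0.844, adjusted p = 0.844). Without the C-type isoforms the differences were -0.32 for beta minus gamma (exact sign-flip adjusted p = 0.328) and -0.84 for alpha minus gamma (exact sign-flip adjusted p = 0.246), and neither passed the threshold. Leaving out colony 2, 3, 4, 5, 6 or 8 brought the adjusted exact p of alpha minus gamma to 0.0703.

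**Figure D2:**
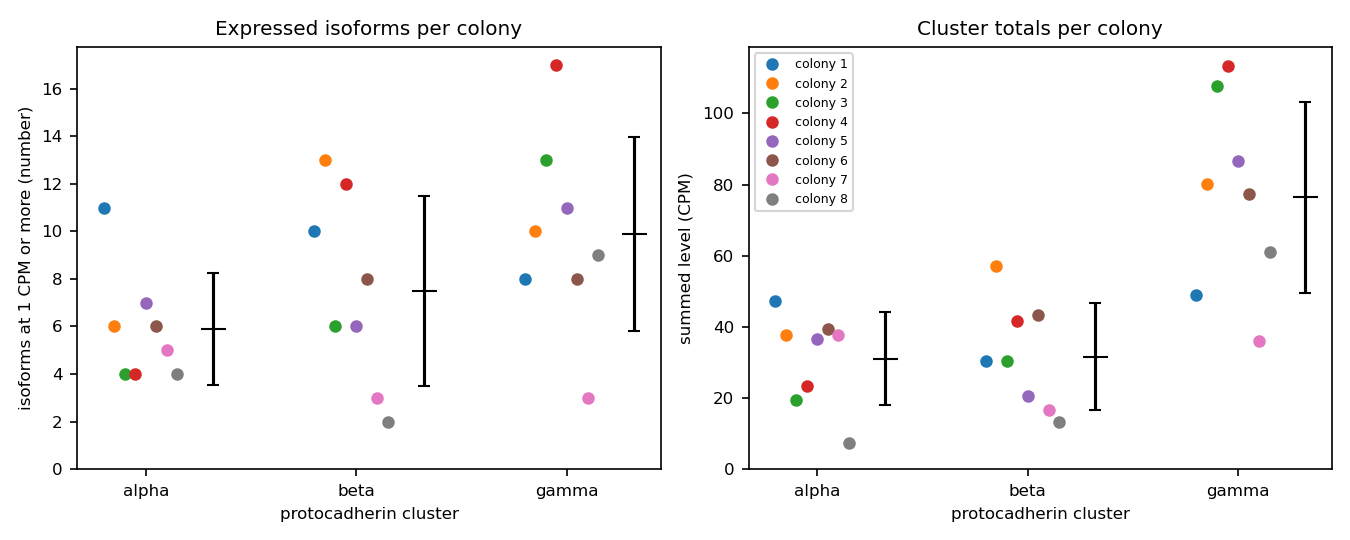
Number of isoforms at 1 CPM or more (left) and summed level in CPM (right) of the alpha, beta and gamma clusters, with 1 point per colony and the mean ± SD over 8 colonies in black. Gamma totals averaged 76.4 CPM, against 31.7 for beta and 31.1 for alpha.

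None of the 3 correlations between log2 cluster totals passed. For alpha and beta, Pearson r was 0.49 (exact permutation p = 0.222, adjusted 0.333) and Spearman rho 0.29 (exact permutation p = 0.501, adjusted 0.501), and r was -0.21 without the 2 colonies farthest from the median of alpha. For alpha and gamma, r was -0.19 (exact permutation p = 0.663, adjusted 0.663), rho -0.52 (exact permutation p = 0.197, adjusted 0.365), and r was -0.65 without the 2 farthest colonies. For beta and gamma, r was 0.52 (exact permutation p = 0.193, adjusted 0.333), rho 0.48 (exact permutation p = 0.243, adjusted 0.365), and r was 0.59 without the 2 farthest colonies.

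Clustered protocadherins were then compared with other genes of like abundance for their variability between colonies, as the log2 ratio of a gene's quasi-dispersion to the trend (edgeR). Under the planned filter, which kept genes with enough counts in every colony, 6 of the 53 isoforms could be tested. They were PCDHA10, PCDHA11, PCDHB2 and the C-type genes PCDHAC1, PCDHAC2 and PCDHGC3, with no gamma A or gamma B isoform, so most variable isoforms were left out. The median ratio of these 6 was 1.84, against 0.24 for random lists matched on abundance (adjusted p = 0.0338 over 20 lists, edgeR ratios against 10000 random lists). Among genes with a mean of 1 CPM or more, 35 isoforms could be tested, with a median of 2.71 against 0.11 (adjusted p = 0.000771 over 27 lists, edgeR ratios against random lists). There the gamma B isoforms had a median of 3.30 (7 tested, adjusted p = 0.0018), gamma A 2.77 (8 tested, adjusted p = 0.0018), beta 2.61 (12 tested, adjusted p = 0.000771) and the variable alpha isoforms 2.51 (5 tested, adjusted p = 0.0405, and 0.0750 without colony 6). The C-type isoforms had a median of 1.51 (3 tested, adjusted p = 0.270). These medians leave out isoforms with a mean under 1 CPM, whose log2 ratios in the fit without a filter ranged from -1.12 to 2.57. Some of the 35 passed through few colonies, such as PCDHB7, which reached 1 CPM in 2 colonies. The medians therefore do not describe all 53 isoforms. No isoform was called by itself over all genes under either filter, and 0 were called adjusted over the list of 53 alone, while 1 of the 7 gamma B isoforms was called adjusted over that list alone at a mean of 1 CPM (edgeR). Without a filter, PCDHGB4 was called over all genes (edgeR adjusted p = 0.0474). At an unadjusted p under 0.05 there were 0 of 6 and 8 of 35. Under the planned filter the call was lost by log variance in place of the quasi-dispersion (median 1.69, adjusted p = 0.0584) and without colonies 2, 3 and 4 (adjusted p = 0.0592, 0.0654 and 0.0943), and the random lists do not carry the correlation between genes of a list, so that all of these p-values may be too small.

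**Figure D3:**
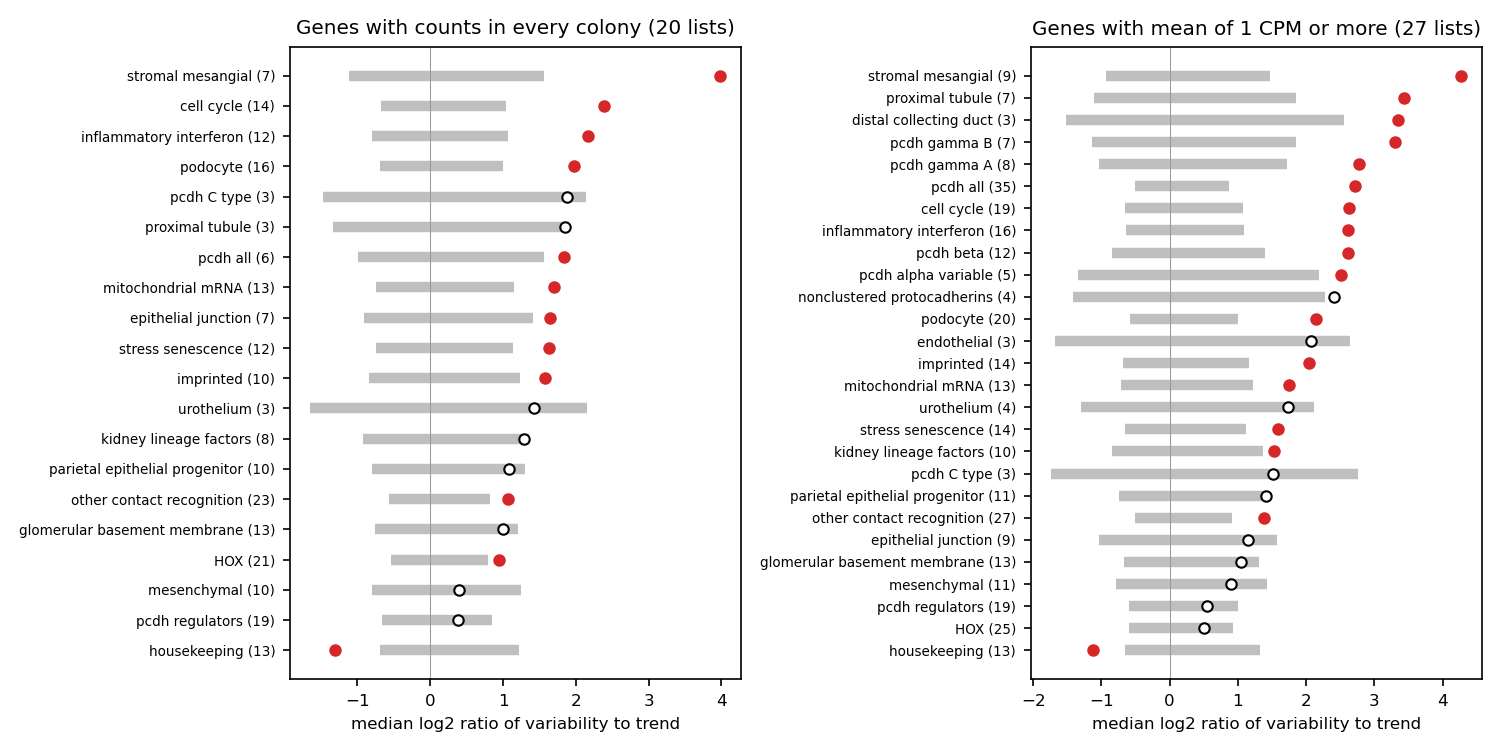
Median log2 ratio of variability to the trend for each gene list (points, filled where the adjusted p was under 0.05). Grey bars give the 95% range of 10000 matched random lists. The panels hold genes with enough counts in every colony (left, 20 lists) and genes with a mean of 1 CPM or more (right, 27 lists). The number of genes tested stands in parentheses, and clustered protocadherins lay at 1.84 on the left and 2.71 on the right.

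Variability above the trend was not limited to protocadherins. Of the 20 lists under the planned filter, 11 were more variable than random lists (8 to 13 when a colony was left out, 8 by log variance and 9 by DESeq2 dispersion) and the housekeeping list was less variable, at -1.31 (adjusted p = 0.0064). The stromal and mesangial list had the highest median at 3.99 (adjusted p = 0.00133), followed by cell cycle genes at 2.39 (adjusted p = 0.00133), inflammatory and interferon genes at 2.17 (adjusted p = 0.00133) and podocyte genes at 1.98 (adjusted p = 0.002, and 1.05 with an adjusted p of 0.0569 without colony 8). Mitochondrial mRNA stood at 1.70 (adjusted p = 0.0127), epithelial junction genes at 1.64 (adjusted p = 0.0417), stress and senescence genes at 1.63 (adjusted p = 0.0131), imprinted genes at 1.57 (adjusted p = 0.0253), other contact recognition genes at 1.07 (adjusted p = 0.0253) and HOX genes at 0.94 (adjusted p = 0.0308). Besides the podocyte and protocadherin lists, calls were lost for epithelial junction genes without colony 3, 4 or 7 (adjusted p = 0.0687, 0.127 and 0.0625), HOX genes without 1, 3, 7 or 8 (adjusted p = 0.0555, 0.172, 0.148 and 0.126), other contact genes without 4 or 7 (adjusted p = 0.346 and 0.0536) and imprinted genes without 4 (adjusted p = 0.0937; edgeR ratios against random lists). Cohesin, CTCF and DNA methylation genes, which control protocadherin promoters, were near random lists at 0.38 (adjusted p = 0.460). At a mean of 1 CPM, 16 of 27 lists were more variable than random lists (14 to 18 lists when a colony was left out), so protocadherins were 1 of many there too. HOX genes (0.51, adjusted p = 0.310) and epithelial junction genes (1.15, adjusted p = 0.173) no longer passed at that filter, and proximal tubule genes did (3.44, adjusted p = 0.000771). Adjusted over the list alone, the calls were 5 stromal, 3 basement membrane and 1 each of podocyte, cell cycle, epithelial junction and imprinted genes, and over all genes there were 0 in each list (edgeR).

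The profile of a colony over the 53 isoforms was less like that of other colonies than profiles over random lists. The mean Pearson r over the 28 pairs, across genes, was 0.514, against 0.744 for matched random lists (95% range 0.660 to 0.818), and the two-sided permutation p of 0.0002 was the smallest that 10000 lists can give. Genes within a list are not independent replicates.

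Position along the clusters was compared with level because the promoters are arranged in order. In the alpha cluster, isoforms farther along had higher mean levels, with a Spearman rho of 0.73 across 15 genes (permutation p = 0.00311, adjusted p = 0.0187 over 6 relations) and reached the threshold in more colonies (rho 0.62, permutation p = 0.0151, adjusted p = 0.0451). Without PCDHAC1 and PCDHAC2, the last genes of the cluster, rho was 0.64 (permutation adjusted p = 0.122) and 0.48 (permutation adjusted p = 0.224). The beta and gamma clusters showed no such relation for mean level, with rho of -0.17 (permutation adjusted p = 0.758) and 0.17 (permutation adjusted p = 0.758). Genes are not independent replicates here either. Neighbouring isoforms had a mean r over colonies of 0.415 in the beta cluster, against 0.263 for all beta pairs (permutation p = 0.0276, adjusted p = 0.0828 over 3 clusters), of 0.450 against 0.373 in alpha (permutation adjusted p = 0.320) and of 0.240 against 0.221 in gamma (permutation adjusted p = 0.763), so none passed.

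Markers were used to describe what the colonies resembled. Parietal epithelial and progenitor genes were abundant, with KRT19, a simple epithelial keratin, at 1765 ± 434 CPM, VCAM1, an adhesion molecule, at 539 ± 212 CPM, CLDN1, a tight junction protein of parietal cells, at 480 ± 186 CPM and PAX8, a kidney lineage factor, at 275 ± 75.6 CPM (SD, n = 8). Podocyte genes were mixed. ACTN4, an actin crosslinker, had 462 ± 98.4 CPM, EZR, a membrane to actin linker, 299 ± 148 CPM, and KIRREL1, a slit diaphragm protein, 154 ± 25.96 CPM (SD, n = 8). WT1, a transcription factor of podocytes, had 27.2 ± 22.9 CPM (SD, n = 8), whereas NPHS1, which encodes the slit diaphragm protein nephrin, had 0.0812 ± 0.0868 CPM (SD, n = 8) and at most 4 counts in any library. Of the 28 podocyte genes, 14 reached 1 CPM in all 8 colonies, 7 in some and 7 in none.

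The median log2(CPM + 0.5) of the podocyte list was 2.62 ± 0.61 (SD, n = 8). It was lower than that of the parietal list in all 8 colonies (8.19 ± 0.45; difference -5.56 ± 0.96, SD, n = 8) and lower than that of the stromal and mesangial list (3.604 ± 1.29; difference -0.98 ± 0.83, SD, n = 8). It was higher in all 8 colonies than those of proximal tubule (by 3.33), loop of Henle (3.48), distal and collecting duct (3.46), urothelium (3.31), squamous epithelium (3.61) and endothelium (3.27). These 6 lists lay near the value of 0 CPM, so the size of the difference depends on the CPM added: with 2 CPM in place of 0.5 the differences were 1.87, 1.92, 1.91, 1.87, 1.95 and 1.86. Each of the 8 contrasts had an exact sign-flip p of 0.00781 and an adjusted p of 0.00781, the smallest that 8 colonies allow. The median of a list depends on which genes it holds, so these p-values do not tell which cell type the colonies resemble. The glomerular basement membrane list stood at 7.56 ± 0.27 (SD, n = 8), with COL4A1, a type IV collagen chain, at 842 ± 418 CPM. The kidney lineage list stood at 1.13 ± 0.85 and the mesenchymal list at 5.62 ± 0.27, with the leukocyte list at -0.91 ± 0.07 (SD, n = 8). Members of the low lists were present all the same: UPK1B, a urothelial plaque protein, had 86.9 ± 34.2 CPM, and MME, a membrane peptidase of tubule and podocyte, ranged from 0.646 CPM in colony 1 to 284 in colony 2.

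**Figure D4:**
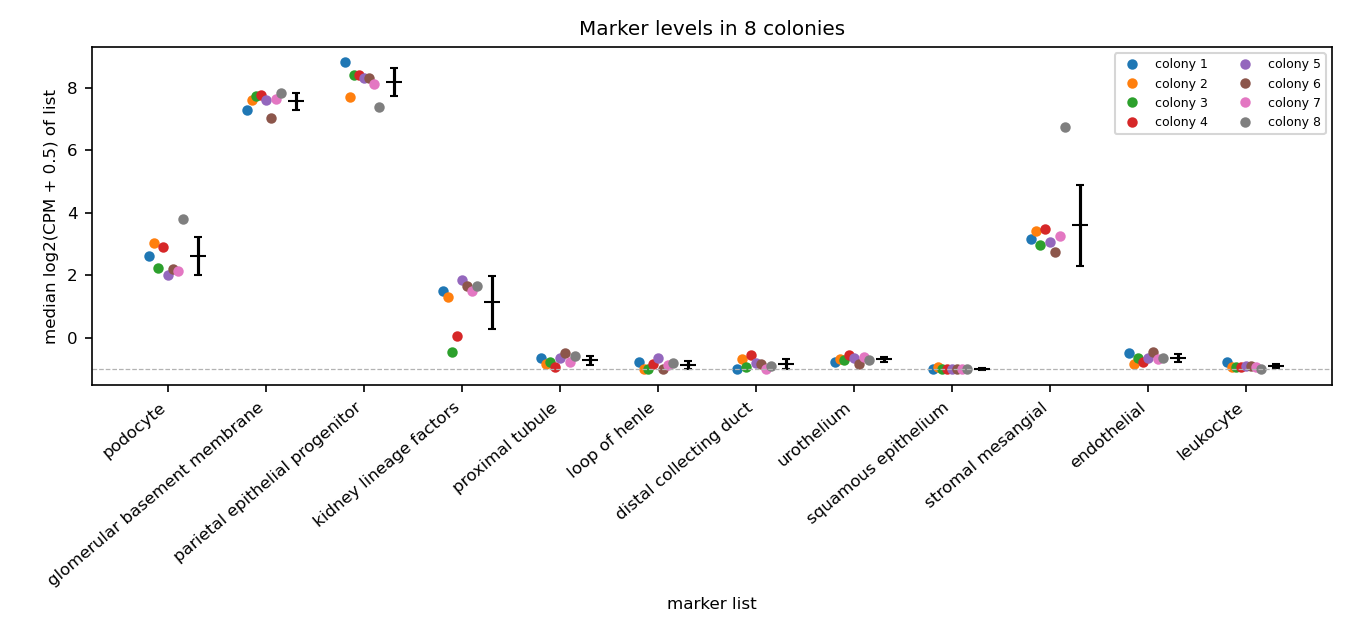
Median log2(CPM + 0.5) of 12 marker lists in each of 8 colonies (points) with the mean ± SD (black), the dashed line marking a CPM of 0. Parietal (8.19) and basement membrane (7.56) lists lay highest, and the stromal list of colony 8 (6.74) lay apart from the other colonies.

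Genes of any kind that varied between colonies more than the abundance trend were sought with edgeR. At an adjusted p under 0.05, 0 of 12442 genes were called, with 628 genes at an unadjusted p under 0.05, 0 called by the variance of log2 values and 106 by the dispersion outliers of DESeq2. In simulated counts with the scatter of the real fit, 0% of genes with an added log2 SD of 2 were recovered after adjustment and 84% had an unadjusted p under 0.05, so this count cannot show that no gene varied. Among the 25 genes with the highest ratios, POSTN, which encodes the matrix protein periostin, ranged from 2.42 CPM in colony 3 to 1354 in colony 5. KRT7, a keratin of simple epithelia, ranged from 2.53 CPM in colony 8 to 274 in colony 3 (log2 ratio 5.67, edgeR unadjusted p = 0.00123, adjusted p = 0.939). SLCO1A2, an organic anion transporter, ranged from 1.14 CPM in colony 4 to 268 in colony 6, and KCNJ15, a potassium channel, from 1.74 in colony 3 to 251 in colony 5. LUM, a matrix proteoglycan, had 492 CPM in colony 7 and 363 in colony 5, but 8.78 in colony 3. PODXL, the main sialoprotein of the podocyte surface, had 56.8 CPM in colony 8 and at most 4.51 elsewhere, and PDGFRB, a receptor of mesangial and stromal cells, had 147 CPM in colony 8 and at most 14.9 elsewhere. SST, a peptide hormone, ranged from 2.67 CPM in colony 3 to 433 in colony 8, and CD177, a surface glycoprotein, from 1.54 in colony 8 to 128 in colony 6. RN7SL471P, with 592 CPM in colony 3 and 0.917 in colony 2, is a pseudogene with near-identical copies, so its count is uncertain.

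Of 39 HOX genes, which record position along the body axis, 17 reached 1 CPM in all 8 colonies, led by HOXA9 at 27.6 ± 5.97 CPM and HOXB7 at 23.4 ± 4.72 CPM (SD, n = 8), 13 in some and 9 in none. HOXA11 had 8.76, 1.22, 8.84, 11.2 and 11.6 CPM in colonies 1, 2, 3, 4 and 8 and lay at or under the level that a count of 0 allows in colonies 5, 6 and 7. HOXD10 had 13.5 CPM in colony 3 and 13.6 in colony 4, 1.01 in colony 1, and lay at or under that limit in the remaining 5. HOXD8 had 11.1 to 23.2 CPM in colonies 1 to 7 and 0.0768 in colony 8. HOXA11, HOXD10 and HOXD8 were singled out after their values were seen, and exons of other genes overlap 31.1%, 16.8% and 0% of their exonic bases.

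**Figure D5:**
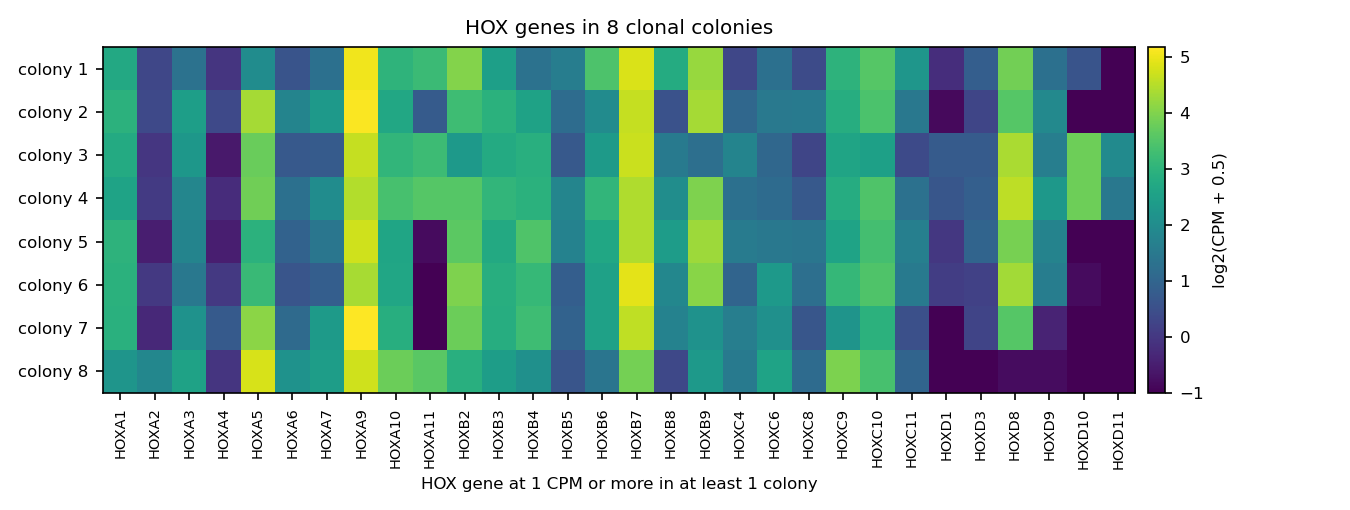
Level of the 30 HOX genes that reached 1 CPM in at least 1 colony, as log2(CPM + 0.5) on the colour scale, with genes on the horizontal axis and the 8 colonies as rows. HOXA9 and HOXB7 were high in every colony, while HOXA11, HOXD8, HOXD10 and HOXD11 were at the floor in some.

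Genes of the cell cycle differed between colonies. TOP2A, a topoisomerase of dividing cells, had 1.22 CPM in colony 2, 1.501 in colony 4 and 85.6 in colony 8, and CCNA2, cyclin A2, ranged from 0.660 CPM in colony 4 to 31.0 in colony 8. The median log2 level of this list ranged from 0.78 in colony 2 to 5.43 in colony 8, and was 4.36 in colony 7, the next highest. Of the 19 genes, 17 were highest in colony 8, against 17.7% of all 12442 genes with enough counts in every colony. The 19 genes were not filtered in this way. In the inflammatory list CXCL1, a neutrophil chemoattractant, had 11.1 CPM in colony 8 and 120 to 385 CPM elsewhere, and CCL2, a monocyte chemoattractant, ranged from 5.80 to 106 CPM. CXCL8, interleukin 8, from the stress list, had 8.75 CPM in colony 8 and 183 to 2719 CPM elsewhere. Among imprinted genes, which are expressed from 1 parental copy, MEST ranged from 0.813 CPM in colony 7 to 150 CPM in colony 8.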

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

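A value was marked for a closer look when the highest or lowest of the 8 colonies lay far from all others for the range of the group. Of 177 values tested, 30 met this rule, and 17 of the 30 were in colony 8. If chance marked 1 value in 20, 8.85 would be expected. Values of genes in 1 list are not independent, so the number expected is a rough guide. Many of the genes tested were also named for their high variability ratio in these same data. The 30 marks therefore cannot be read as an excess over chance.

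Colony 8 lay apart with a log2 alpha total of 2.87, a stromal and mesangial median of 6.74, and, in CPM, PCDHA10 1.497, EPHB2 360.1, TET1 25.5, PODXL 56.8, LRP2 45.3, CLDN16 0.806, AQP3 9.37, PDGFRB 147, HOXB7 14.3, HOXD8 0.0768, CXCL8 8.75, CDKN1A 139, CXCL1 11.1, ICAM1 37.2 and ABI3BP 74.9. Colony 3 had the highest total of 31881089 counts, the fewest genes at 1 CPM (12919) and the highest TRPM6 (3.94 CPM). Colony 6 had the highest PCDHGA10 (13.5 CPM) and PCDHGA11 (11.4 CPM). Colony 4 had the highest PCDHGC5 (2.22 CPM), ACTN4 (681 CPM) and KIRREL1 (214 CPM). Colony 1 had the highest leukocyte median (-0.76), PPIA (1873 CPM) and KRT4 (0.185 CPM). The squamous median was highest in colony 2 (-0.92) and SBSN in colony 7 (0.163 CPM). KRT4, SBSN, the leukocyte median of colony 1 and the squamous median of colony 2 lie within what a count of 0 allows.

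For the patterns below, no biological explanation was tested, because the labels give 1 group. The tests of counting noise, of 1 library standing apart and of admixed stromal cells were chosen only after the results were seen, and those of shared reads, depth and overlapping genes were written before.

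Clustered protocadherins varied between colonies more than genes of like abundance. Counting noise of independent reads is unlikely to be the cause: the chi-square per degree of freedom of 35 isoforms had a median of 48.1 (16.8 to 381; 95% bound 2.01), and the random lists, matched on abundance, carry like noise. Genes in general exceed that bound, so the value does not speak to other technical noise. At a mean of 1 CPM the median ratio of the list was 2.50 to 3.01 without 1 colony, against 2.71 with all, above the random lists each time (highest adjusted p 0.00108, with the unadjusted p at its smallest value of 0.0002 throughout), but under the planned filter, with 6 isoforms, the adjusted p was 0.0592, 0.0654 and 0.0943 without colonies 2, 3 and 4 (edgeR ratios against random lists). Reads shared between similar isoforms might contribute: the percent of shared words and the log2 ratio had a Spearman rho of 0.18 across 35 isoforms (permutation p = 0.297), with a median of 10.1% shared, which leaves this open.

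Colony 8 lay apart in many genes. Depth is unlikely to be the cause, since 13 of 15 genes still met the rule after all libraries were thinned to the smallest total. Thinning keeps the composition of a library, so it does not speak to differences in composition. Stromal cells diluting the epithelial cells may account for some low genes: the parietal list had a median log2 ratio of -0.47 (SD 1.33 over 10 genes), and the 8 low genes, at a median of -2.08, were selected as low, so their gap to the list leaves this open. For the genes that were high, admixed stromal cells may still account for part, as 6 of the 12 stromal and mesangial genes were highest in colony 8: PDGFRB (147 CPM, at most 14.9 elsewhere), COL3A1 (116, at most 2.95), ACTA2 (47.0, at most 21.7), COL1A2 (19.8, at most 9.15) and, by little, COL1A1 (271, at most 249.7) and THY1 (843, at most 776). DCN, LUM, TAGLN, DES, PDGFRA and ITGA8 were not highest there, and the list holds genes that cultured kidney epithelial cells can also express.

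HOXA11, HOXD8 and HOXD10 were on in some colonies and at the floor in others, and these 3 were chosen after their values were seen. A median chi-square per degree of freedom of 88.7 (88.0 to 190) lies beyond counting noise, but choosing genes that were on and off made it large, and it does not speak to other technical causes. Reads from overlapping or antisense genes could contribute, since exons of other genes overlap a median of 16.8% of their exonic bases (0 to 31.1), and the data do not settle this for HOXA11 and HOXD10. No base of HOXD8 is overlapped.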

How the results depend on the processing

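Of the main values under alternatives, 259 kept their direction and their side of the threshold, 4 moved, 2 became stronger, 14 weaker and 11 reversed. The cause of the changes below was not tested, except where fewer colonies or genes raise the smallest p. Totals without mitochondrial rRNA, the equal-chance model, the robust prior, the filter at a mean of 1 CPM with each colony left out, position without C-type genes and counts per unshared exonic base were chosen after seeing the data.

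The number of isoforms was 31.0 at 0.5 CPM and 7.75 at 5 CPM (21.9 to 25 without 1 colony). Sharing lay within the random range in the planned analysis (0.433 against a random mean of 0.432). It also lay within that range, but under the random mean, with total counts (0.435, permutation p = 0.895), 10 raw reads (0.518, permutation p = 0.219) and without colony 8 (0.457, permutation p = 0.285). It passed at 0.5 CPM (0.540, permutation p = 0.0194) and with equal chance (0.433, permutation p = 0.001). Without 1 colony it ranged from 0.411 to 0.468. Alpha minus beta ranged from -0.22 to 0.0603 and turned positive without colony 2 (0.0267), 3 (0.0306), 4 (0.0595) or 8 (0.0603). Alpha minus gamma ranged from -1.57 to -1.14 and missed the threshold without 2, 3, 4, 5, 6 or 8 (exact adjusted p = 0.0703), and without C-type isoforms it was -0.84 (exact adjusted p = 0.246) and beta minus gamma -0.32 (exact adjusted p = 0.328). Per unshared exonic base PCDHA10 led in 1 colony rather than 7, while totals, their correlations and position kept their calls. The alpha and beta correlation ranged from -0.11 (without 8) to 0.65.

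Hypervariable genes numbered 79 without a filter (edgeR) and 106 by DESeq2, and 0 without any 1 colony. The protocadherin list had a median ratio of 1.69 by log variance (adjusted p = 0.0584) and of 1.80, 1.73 and 1.66 without colonies 2, 3 and 4 (adjusted p = 0.0592, 0.0654 and 0.0943), with a range of 1.65 to 2.24. Regulators ranged from -0.0440 (without 8) to 0.50, and mesenchymal genes from -0.12 (without 4; -0.0367 without 2) to 0.84. Alpha position without C-type genes had rho 0.64 (permutation adjusted p = 0.122) and 0.48 (permutation adjusted p = 0.224). Gamma neighbours ranged from 0.158 to 0.382 and fell below all pairs without 3 (0.208) and 5 (0.228). Isoform number against depth was 0.30 with 10 raw reads (exact permutation p = 0.411). Among other values, 1870 were unchanged in direction and call, 34 moved, 8 became stronger, 18 weaker and 3 reversed. The podocyte list had 1.05 without colony 8 (adjusted p = 0.0569).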

Other observations

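CLIC5, FOXC1 and PLA2R1 and the statements on colony 8 in this part were chosen after the values were seen. Of the podocyte genes, CLIC5, a chloride channel protein of foot processes, had 275 CPM in colony 8 and at most 4.52 elsewhere, PODXL 56.8 against 4.51, WT1 79.1 against 28.5, FOXC1, a transcription factor, 119 against 36.5, and PLA2R1, a surface receptor, 60.7 against 31.5. Of the 28 podocyte genes, 16 were highest in colony 8 and 2 lowest, among them EZR, with 89.6 CPM there and 152 to 535 elsewhere. The share was 57.1%, against 89.5% of cell cycle genes, 68.4% of regulators of protocadherin promoters and 50.0% of stromal and mesangial genes. Of the 12442 genes with enough counts in every colony, 17.7% were highest in colony 8. That filter was not applied to the lists, whose shares count all members, so the 17.7% is not a like background. No test was made. Markers of other cell types were high in the same colony, with PDGFRB at 147 CPM (at most 14.9 elsewhere), COL3A1 at 116 CPM (at most 2.95) and LRP2, a receptor of the proximal tubule, at 45.3 CPM (at most 0.141). NPHS1 had a count of 0 there. MKI67, a marker of dividing cells, ranged from 0.122 CPM in colony 2 to 65.6 in colony 8.

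Of the lists the report leaves out, nonclustered protocadherins had a median log2 level of -0.54 ± 0.11 (SD, n = 8), with PCDH9 at 13.6 ± 3.10 CPM. Other contact genes stood at 3.55 ± 0.30, with FAT1, a giant cadherin, at 645 ± 135 CPM, and TENM2, a teneurin, at 62.0 ± 42.0 CPM (SD, n = 8). Regulators of protocadherin promoters stood at 4.74 ± 0.37, all 19 at 1 CPM or more in all 8 colonies, with PDS5A, a cohesin partner, at 115 CPM and TET1, a DNA demethylase, at 6.19 ± 7.83 CPM (SD, n = 8). Stress genes stood at 4.76 ± 0.46, inflammatory genes at 4.17 ± 0.61, imprinted genes at 2.33 ± 0.65, mitochondrial mRNA at 6.67 ± 0.75, housekeeping genes at 8.97 ± 0.29, HOX genes at 1.30 ± 0.28, cell cycle genes at 3.09 ± 1.53 and epithelial junction genes at 1.73 ± 0.35 (SD, n = 8). At a mean of 1 CPM the median variability ratio was 2.41 for nonclustered protocadherins (adjusted p = 0.0576) and 2.08 for endothelial genes (adjusted p = 0.159; edgeR ratios against random lists). Under the planned filter it was 1.28 for kidney lineage factors (adjusted p = 0.0903), 1.00 for basement membrane (adjusted p = 0.130), 1.08 for parietal (adjusted p = 0.145), 1.42 for urothelium (adjusted p = 0.223) and 0.40 for mesenchymal genes (adjusted p = 0.705; edgeR ratios against random lists).

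As a hypothesis, not part of the study's labels, colonies with similar transcriptomes could use similar protocadherin sets. The prediction was written before the test. Over the 28 pairs, the correlation of transcriptomes without clustered protocadherins and the Jaccard index of isoform sets had a Pearson r of 0.0822 (exact permutation p = 0.811) and a Spearman rho of 0.03, so the test neither favours the hypothesis nor excludes it.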
